A study of Homo sapiens with 6 samples.

How the data were processed

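Gene expression was measured by RNA-seq of total RNA from MCF7 cells, isolated with a column kit per the labels' protocols, in 6 libraries: 2 of cells in DMSO, 2 in abemaciclib (500 nM) and 2 in abemaciclib (500 nM) with SR11302 (20 uM), each for 7 days. Per the labels, cells were plated so that cultures reached a similar density at harvest. The deposited values were whole-number read counts per gene symbol, not normalised, as the table's column names and values show. The genome build was hg19, per the submitters' processing notes. The aligner, the counting program, the annotation and whether counting used strand are not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies, carry that uncertainty. Columns were matched to samples by treatment and number. Abemaciclib columns carried the prefix of the maker's development code for abemaciclib, and combination columns carried that prefix with the prefix of SR11302. No column was left out. Library totals were 20597562 and 23524954 reads for DMSO, 22132933 and 18565446 for abemaciclib, and 19419831 and 22286694 for the combination.

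Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as design, which left 12823 of 20125, and libraries were scaled by TMM. The negative binomial model had a mean for each of the 3 groups and was fitted to all 6 libraries, so that the groups shared an estimate of spread (biological coefficient of variation 5.07%, 3 residual degrees of freedom, prior degrees of freedom 14.7). These contrasts were tested with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05: abemaciclib against DMSO, the combination against abemaciclib, and the combination against DMSO. The SE of a log2 fold change was its size divided by the square root of the F statistic. For genes at 0 reads in a group, a floor of 3 counts over the group gave a bound on the fold, and genes at 1 to 3 reads have a ratio with its 95% counting interval.

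Before the data were examined, 25 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were DNA replication and G1/S genes, G2/M and mitosis genes, cyclins with CDKs, their inhibitors and the RB family, AP-1 subunits, reported AP-1 targets, immediate-early genes, estrogen receptor targets, luminal identity genes, basal and mesenchymal genes, type I interferon response genes, MHC class I antigen presentation genes, p53 targets, senescence secretory genes, anti-apoptotic and pro-apoptotic BCL2 family genes, retinoic acid response genes, cholesterol synthesis genes, fatty acid synthesis genes, lysosome genes, unfolded protein and integrated stress response genes, NRF2 targets, hypoxia and glycolysis genes, markers of other cell types, mitochondrially encoded transcripts and ribosomal protein genes. Of 651 entries, 646 matched a symbol in the table, 3 of them through a synonym, and the other 5 were not analysed here. Matched members with too few reads were not tested either, which left some lists short. Those measured were 17 of 35 AP-1 targets, 8 of 24 senescence genes, 11 of 24 basal and mesenchymal genes and 5 of 24 markers of other cell types. Lists were tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 25 lists, and again with an estimated correlation. Named genes were, for each comparison, up to 10 higher and 10 lower genes with the largest change among those past the threshold, with a mean of at least 5 CPM and no overlap between libraries of the groups, up to 4 members of each list with the smallest p, and 28 genes fixed in advance.

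The test was checked on counts simulated for 12823 genes with known changes. At a 2-fold change it recovered 92% of changed genes for abemaciclib against DMSO, 86% for the combination against abemaciclib and 89% for the combination against DMSO. At a 1.5-fold change it recovered 71%, 72% and 73%, with 15, 4 and 5 false calls, and camera called 0 of 50 unchanged lists in each. Simulated genes were drawn independently, with 100 changed at each fold, far fewer than were called in the data. The check therefore says nothing of lists whose members moved together, such as ribosomal protein genes (estimated inter-gene correlation 0.89 with abemaciclib). Alternatives were RLE size factors, scaling by library size only, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, only the 4 libraries compared, a replicate block, leaving out each library in turn, and fry of limma for the lists. A test against a fold of 1.2, leaving out mitochondrially encoded genes, and a crossed block were added after the data were seen, as were 8 further gene lists used in the closing section. A reference genome of another build than hg19 was used only for gene synonyms and for transcript length and GC content by symbol, so no coordinates are given.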

Results

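The data were read counts from 6 RNA-seq libraries of MCF7, an established estrogen receptor-positive breast carcinoma line. Cells had been kept for 7 days in the vehicle DMSO, in 500 nM abemaciclib, or in 500 nM abemaciclib with 20 uM SR11302, with 2 libraries in each group. Abemaciclib is an inhibitor of the kinases CDK4 and CDK6, and SR11302 is a retinoid that represses the AP-1 transcription factor. A group given SR11302 alone was not analysed here. Library totals ran from 18565446 (abemaciclib replicate 2) to 23524954 (DMSO replicate 2) counted reads. Of 20125 gene symbols in the table, 12823 had enough reads to be tested. The groups separated on the leading principal components of log2 expression, which held 64.9% and 31.6% of the variance. Replicates differed by more than sampling noise in every group (chi-square per degree of freedom 2.28 for DMSO, 7.53 for abemaciclib and 7.14 for the combination), so none looked like a library deposited again. Log2 fold changes are given ± SE from edgeR, and expression levels as TMM-normalised CPM, mean ± SD over the 2 libraries. The count of a list's members past the threshold, adjusted over the list alone, is given beside the count adjusted over all genes where they differ; elsewhere the numbers were the same.

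The comparison of abemaciclib with DMSO addressed how CDK4/6 inhibition altered gene expression in MCF7 cells. After 7 days of abemaciclib, genes of mitosis and DNA replication were lower, and estrogen receptor targets, interferon response genes, lysosome genes and fatty acid synthesis genes were more often higher than lower. Of the 40 measured genes of G2/M and mitosis, 0 rose, 39 fell and 1 did not pass. Their median was -1.26 (camera adjusted p = 1.38e-38, adjusted p = 0.0636 with an estimated correlation). TOP2A, the topoisomerase that untangles replicated chromosomes, fell from 440.3 ± 3.82 to 104 ± 7.2 CPM (-2.08 ± 0.064, edgeR adjusted p = 2.48e-14). NDC80 (-2.15 ± 0.085), FOXM1 (-1.50 ± 0.066) and MKI67 (-1.29 ± 0.066), which encode a kinetochore component, a mitotic transcription factor and the Ki-67 antigen, fell too. Among 51 DNA replication and G1/S genes regulated by E2F, 2 rose, 44 fell and 5 did not pass. Their median was -0.73 (camera adjusted p = 8.22e-14, adjusted p = 0.0975 with an estimated correlation). The licensing factor CDT1 (-2.57 ± 0.083), the ribonucleotide reductase subunit RRM2 (-1.46 ± 0.064) and E2F1 itself (-0.88 ± 0.084) were among those that fell. Of 15 cyclins, CDKs, CDK inhibitors and RB family members, 4 rose, 11 fell and 0 did not pass. Their median was -0.55 (camera adjusted p = 0.0405, adjusted p = 0.275 with an estimated correlation). That call was also lost without abemaciclib replicate 1 (adjusted p = 0.0651). CDK6 (1.66 ± 0.36) and the cyclin gene CCND1 (0.85 ± 0.058) rose, while CDK4 (-0.71 ± 0.065), CCNE2 (-0.63 ± 0.17) and the p27 gene CDKN1B (-1.50 ± 0.062) fell. The log2 fold change was -0.20 ± 0.056 for the p21 gene CDKN1A, -0.27 ± 0.084 for RB1 and 0.63 ± 0.20 for CCNE1. These calls were lost without DMSO replicate 2 for CDKN1A (-0.19), without DMSO replicate 1 for RB1 (-0.25) and CCNE1 (0.51), and without abemaciclib replicate 2 for CCNE1 (0.54).

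Of the 30 measured estrogen receptor target genes, 24 rose, 4 fell and 2 did not pass (24 rose and 5 fell adjusted over the list alone). Their median was 0.89 (camera adjusted p = 4.49e-13, adjusted p = 0.0636 with an estimated correlation). GREB1, a receptor cofactor, rose from 449 ± 7.73 to 968 ± 86.6 CPM (1.11 ± 0.071). The progesterone receptor gene PGR rose by 1.05 ± 0.073 and the secreted peptide gene TFF1 by 1.46 ± 0.078. The receptor gene ESR1 stood at -0.091 ± 0.062 and did not pass, but did without abemaciclib replicate 2 (-0.16). Luminal identity genes went both ways: of 26, 9 rose, 8 fell and 9 did not pass (10 rose and 9 fell adjusted over the list alone) (camera adjusted p = 0.382). The keratin genes KRT8 (1.46 ± 0.084) and KRT19 (1.45 ± 0.079) rose and ERBB3 (-1.37 ± 0.064) fell. Of 11 basal and mesenchymal genes, 5 rose, 1 fell and 5 did not pass (camera adjusted p = 0.552). KRT15 (3.73 ± 0.21) rose and the fibronectin gene FN1 (-1.17 ± 0.064) fell. Among 17 reported AP-1 target genes, 11 rose, 4 fell and 2 did not pass. Their median was 1.14 (camera adjusted p = 5.38e-04, adjusted p = 0.201 with an estimated correlation). They included the laminin gene LAMC2 (3.63 ± 0.18), the protease inhibitor gene TIMP1 (1.52 ± 0.064) and the EGFR ligand gene AREG (1.49 ± 0.078), all higher. The AP-1 subunits themselves did not move as a group (camera adjusted p = 0.745): of 14, 4 rose, 5 fell and 5 did not pass. FOS (1.42 ± 0.11), JUNB (0.93 ± 0.087) and FOSL2 (0.78 ± 0.069) rose. ATF3 (-1.64 ± 0.13) and JUND (-0.33 ± 0.073) fell. JUN (0.029 ± 0.061) and FOSL1 (-0.31 ± 0.44) did not pass. Of 19 immediate-early genes, 9 rose, 5 fell and 5 did not pass (camera adjusted p = 0.287). MYC fell (-0.54 ± 0.060).

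Type I interferon response genes mostly rose: of 39, 23 rose, 8 fell and 8 did not pass. Their median was 0.54 (camera adjusted p = 0.00201, adjusted p = 0.377 with an estimated correlation). IFI6, an interferon-induced mitochondrial protein gene, rose from 7.16 ± 0.298 to 56.2 ± 7.88 CPM (2.97 ± 0.12). The ubiquitin-like modifier gene ISG15 (1.76 ± 0.13), the RNA sensor gene DDX58 (1.91 ± 0.16) and STAT1 (0.54 ± 0.058) rose too. Of 19 genes of MHC class I antigen presentation, 8 rose, 2 fell and 9 did not pass (camera adjusted p = 0.187). HLA-A (0.75 ± 0.094) and HLA-F (2.25 ± 0.24) rose, with the limit that near-identical HLA genes can share reads. B2M (-0.073 ± 0.060) did not pass, but did without abemaciclib replicate 1 (-0.16). Of 13 fatty acid synthesis genes, 8 rose, 1 fell and 4 did not pass. Their median was 0.51 (camera adjusted p = 7.59e-05, adjusted p = 0.198 with an estimated correlation). The lipogenic regulator gene THRSP (3.47 ± 0.085) and the fatty acid synthase gene FASN (0.91 ± 0.063) were examples. Of 24 cholesterol synthesis genes, 14 rose, 4 fell and 6 did not pass (camera adjusted p = 0.079, and 0.0381 without abemaciclib replicate 2). LSS, the lanosterol synthase gene, rose (0.83 ± 0.058). Of 34 lysosome genes, 21 rose, 5 fell and 8 did not pass. Their median was 0.51 (camera adjusted p = 5.19e-07, adjusted p = 0.242 with an estimated correlation). The protease gene CTSD (2.21 ± 0.076) and the acid lipase gene LIPA (1.32 ± 0.077) rose. Of 25 hypoxia and glycolysis genes, 14 rose, 7 fell and 4 did not pass. Their median was 0.34 (camera adjusted p = 0.0136, adjusted p = 0.229 with an estimated correlation). PFKFB3 (1.45 ± 0.065), a glycolytic regulator gene, and the glucose transporter gene SLC2A1 (1.26 ± 0.066) rose.

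Unfolded protein and integrated stress response genes fell more often than they rose: of 26, 7 rose, 13 fell and 6 did not pass. Their median was -0.21 (camera adjusted p = 4.53e-05, adjusted p = 0.299 with an estimated correlation). The asparagine synthetase gene ASNS (-1.54 ± 0.058) and the pseudokinase gene TRIB3 (-1.81 ± 0.060), both ATF4 targets, fell. Of 30 p53 target genes, 6 rose, 12 fell and 12 did not pass (camera adjusted p = 0.132). Of 20 NRF2 target genes, 4 rose, 6 fell and 10 did not pass (camera adjusted p = 0.745). Of 20 retinoic acid response genes, 7 rose, 3 fell and 10 did not pass (camera adjusted p = 0.149). The retinoic acid hydroxylase gene CYP26B1 rose (3.49 ± 0.18), and CYP26A1 (1.18 ± 0.70) did not pass. The retinaldehyde reductase gene DHRS3 fell (-1.49 ± 0.16). Of 8 senescence secretory genes, 3 rose, 3 fell and 2 did not pass (camera adjusted p = 0.745). The nuclear lamina gene LMNB1 fell (-1.24 ± 0.060). Of 8 anti-apoptotic genes, 2 rose, 2 fell and 4 did not pass (camera adjusted p = 0.932). Of 11 pro-apoptotic BCL2 family genes, 3 rose, 5 fell and 3 did not pass (camera adjusted p = 0.242). BCL2 rose (0.64 ± 0.075), BCL2L11 fell (-0.89 ± 0.075), and BCL2L1 (0.094 ± 0.064) did not pass. MCL1 stood at 0.14 ± 0.056, a call lost in 5 of the 6 fits that left out 1 library (0.12 to 0.14). It was also lost with DESeq2 (0.14), a replicate block (0.14), no low-count filter (0.13) and only the 4 libraries compared (0.14). Ribosomal protein genes, a list kept as a sign of RNA quality, fell: of 40, 0 rose, 37 fell and 3 did not pass. Their median was -0.48 (camera adjusted p = 1.34e-07, adjusted p = 0.458 with an estimated correlation). Their share of reads went from 8.58% ± 0.0413 to 6.21% ± 0.368 (SD, n = 2). Mitochondrially encoded transcripts rose: of 13, 12 rose, 0 fell and 1 did not pass. Their median was 0.67 (camera adjusted p = 4.96e-04, adjusted p = 0.458 with an estimated correlation). Their share went from 4.30% ± 0.162 to 6.71% ± 0.152 (SD, n = 2). Nuclear copies of the mitochondrial genome can share these reads. Of 5 measured markers of other cell types, 4 rose, 0 fell and 1 did not pass (camera adjusted p = 0.132). The fibroblast marker LUM had 0 reads in DMSO and 114 in abemaciclib, at least 41.0-fold higher against a floor of 3 counts over the group. The call of VWF was lost without DMSO replicate 1 (1.75), and that of HBA1 without each of the 4 libraries compared in turn (0.98 to 1.36) and with DESeq2 (1.16).

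The largest rises by the naming rule were in FGFBP2 (4.61 ± 0.15), ADAMTS9 (4.52 ± 0.087), CLIC3 (4.36 ± 0.15), AOX1 (4.24 ± 0.14) and OLFML3 (3.999 ± 0.13). The largest falls by that rule were in BRINP2 (-2.83 ± 0.15), IRS2 (-2.69 ± 0.16), NRM (-2.56 ± 0.10) and UNC5B (-2.53 ± 0.10) beside CDT1. In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 8072 of 12823 genes (62.9%) at an adjusted p of 0.05. Of these, 4044 rose and 4028 fell, and 1179 rose and 672 fell by more than 2-fold. Nothing in the labels says that replicates were separate cultures, so p-values here measure only the spread between these samples, which may be technical. Camera called 12 of the 25 lists, and 0 with an estimated correlation. The sign of the camera direction differed from that of the median for AP-1 subunits, NRF2 targets and senescence genes, none of them called.

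**Figure D1:**
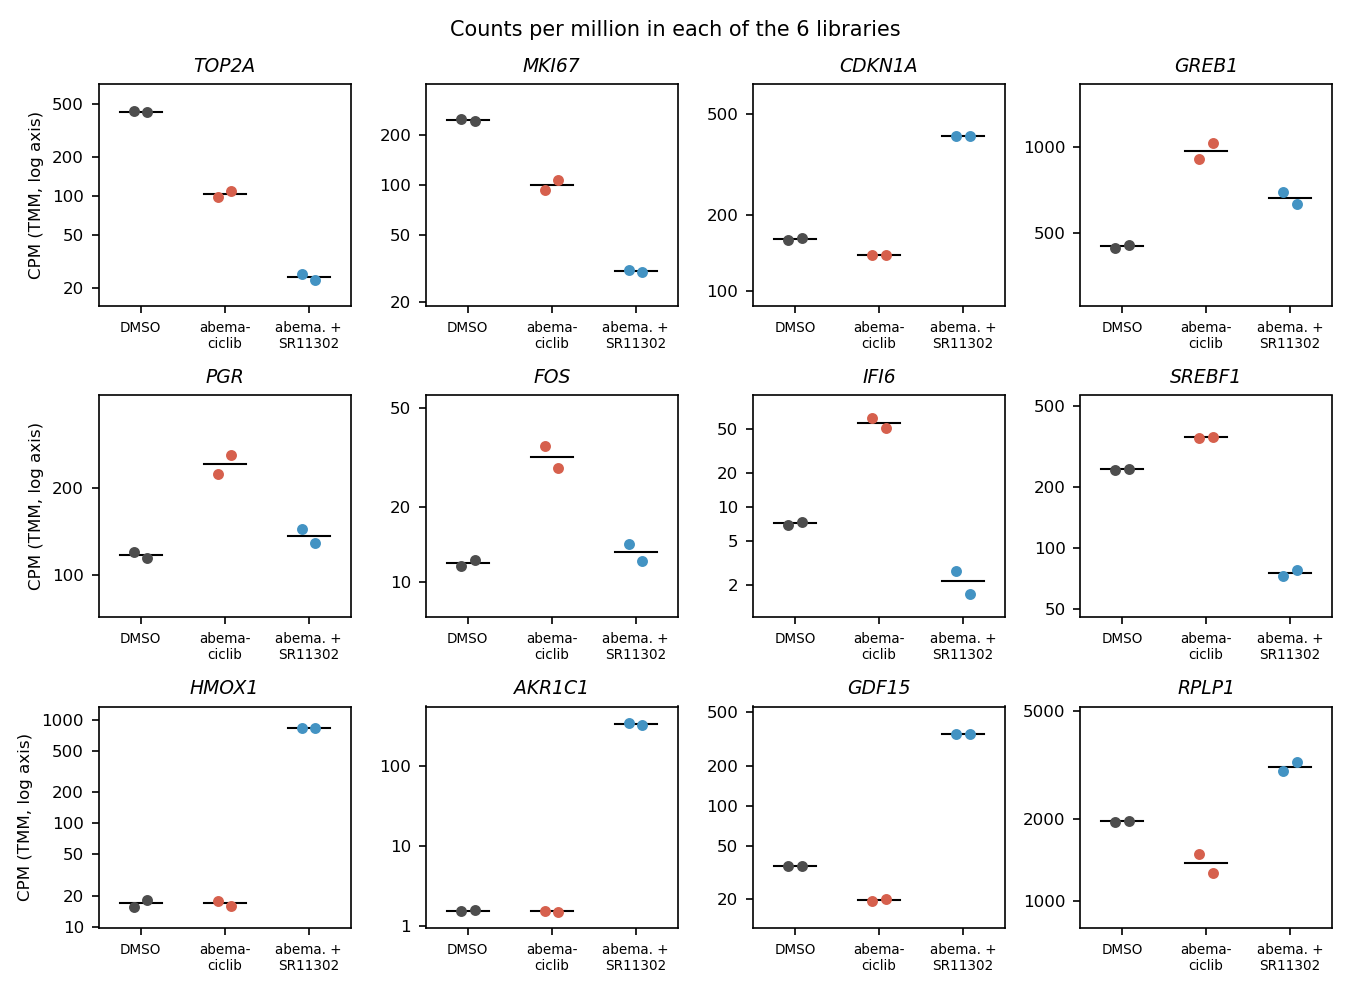
Normalised expression (TMM-normalised CPM, log axis) of 12 genes in each of the 6 libraries, with points for libraries and a bar for the mean of each group of 2. TOP2A stepped down from 440.3 through 104 to 24.1 CPM, IFI6 was highest with abemaciclib (56.2 CPM), and HMOX1 and AKR1C1 were highest with SR11302 added (834 and 342 CPM).

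The combination was compared with abemaciclib alone to ask what SR11302 added in cells under CDK4/6 inhibition. With SR11302, mitotic and replication genes fell further, NRF2 targets rose, and many interferon response, estrogen receptor target and fatty acid synthesis genes fell. Of 40 G2/M genes, 0 rose, 40 fell and 0 did not pass. Their median was -1.94 (camera adjusted p = 1.19e-56, adjusted p = 0.00934 with an estimated correlation). TOP2A fell from 104 ± 7.2 to 24.1 ± 1.6 CPM (-2.11 ± 0.075). The mitotic kinesin gene KIF20A (-2.71 ± 0.11), the separase gene ESPL1 (-2.89 ± 0.11) and MKI67 (-1.72 ± 0.075) fell as well. Of 51 DNA replication genes, 0 rose, 50 fell and 1 did not pass. Their median was -1.02 (camera adjusted p = 5.40e-24, adjusted p = 0.0557 with an estimated correlation). RRM2 (-2.71 ± 0.080), TK1 (-1.79 ± 0.094), E2F1 (-0.91 ± 0.10) and CCNE2 (-1.76 ± 0.24) fell. Of 15 cyclins, CDKs and their inhibitors, 5 rose, 8 fell and 2 did not pass (camera adjusted p = 0.531). CDKN1A rose from 139 ± 0.112 to 408 ± 0.795 CPM (1.55 ± 0.056). CCND1 (-0.62 ± 0.058) and RB1 (-0.42 ± 0.089) fell. The values for CDK6 (0.85 ± 0.27) and CCNE1 (-0.53 ± 0.21) passed. The call of CDK6 was lost without combination replicate 2 (0.80), with scaling on library size only (0.59) and with DESeq2 (0.86). That of CCNE1 was lost without abemaciclib replicate 2 (-0.44) or combination replicate 1 (-0.27) and with DESeq2 (-0.53). CDK4 stood at 0.26 ± 0.066, or -0.0012 when libraries were scaled by size only.

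NRF2 target genes, which encode antioxidant and detoxifying enzymes, rose together with SR11302: of 20, 19 rose, 0 fell and 1 did not pass (20 rose and 0 fell adjusted over the list alone). Their median was 1.43 (camera adjusted p = 1.55e-68, adjusted p = 0.00934 with an estimated correlation). The heme oxygenase gene HMOX1 rose from 16.9 ± 1.36 to 834 ± 8.11 CPM (5.63 ± 0.082, edgeR adjusted p = 2.44e-19). The aldo-keto reductase genes AKR1C1 (7.80 ± 0.10), AKR1C2 (6.34 ± 0.077) and AKR1C3 (6.07 ± 0.093) rose, although these paralogs are similar enough to share reads. CYP1A1, a cytochrome P450 gene induced by aryl hydrocarbons, had 1 read in the abemaciclib libraries and 1433 in the combination. The normalised ratio was 1678 (95% counting interval 301 to 66325). Of 30 p53 targets, 24 rose, 2 fell and 4 did not pass (25 rose and 2 fell adjusted over the list alone). Their median was 0.55 (camera adjusted p = 3.77e-09, adjusted p = 0.0507 with an estimated correlation), or 0.29 with scaling on library size only. GDF15, a stress-induced cytokine gene, rose from 19.8 ± 0.557 to 345 ± 1.29 CPM (4.13 ± 0.067). SESN2, a stress-induced regulator of growth signalling, rose by 1.18 ± 0.062. Of 26 unfolded protein and integrated stress response genes, 20 rose, 4 fell and 2 did not pass. Their median was 0.75 (camera adjusted p = 2.89e-13, adjusted p = 0.115 with an estimated correlation), or 0.49 with scaling on library size only. The stress transcription factor gene DDIT3 (2.39 ± 0.11), the cystine transporter gene SLC7A11 (1.77 ± 0.083) and ASNS (1.21 ± 0.058) rose. These lists share members: SLC7A11 was also in the NRF2 list, and SESN2 was in both the p53 and the stress response list. Of 34 lysosome genes, 19 rose, 4 fell and 11 did not pass. Their median was 0.25 (camera adjusted p = 7.48e-05, adjusted p = 0.251 with an estimated correlation), but -0.015 when libraries were scaled by size only. SQSTM1 (2.58 ± 0.066) and GPNMB (3.31 ± 0.16) rose. Of 24 cholesterol synthesis genes, 17 rose, 2 fell and 5 did not pass (18 rose and 2 fell adjusted over the list alone). Their median was 0.40 (camera adjusted p = 1.36e-04, adjusted p = 0.16 with an estimated correlation), or 0.14 with scaling on library size only. HMGCS1, which acts early in the pathway, rose (0.99 ± 0.060).

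Interferon response genes fell with SR11302: of 39, 2 rose, 27 fell and 10 did not pass (3 rose and 27 fell adjusted over the list alone). Their median was -0.90 (camera adjusted p = 7.77e-06, adjusted p = 0.251 with an estimated correlation). IFI6 fell from 56.2 ± 7.88 to 2.16 ± 0.718 CPM (-4.71 ± 0.16). The tetherin gene BST2 (-1.47 ± 0.092) and the oligoadenylate synthetase gene OAS3 (-1.79 ± 0.12) fell too. STAT1 stood at 0.14 ± 0.057, a call lost in 4 of the 6 fits that left out 1 library (0.11 to 0.17). The call was also lost with DESeq2 (0.15), a replicate block (0.14), no low-count filter (0.15), a mean of at least 5 CPM (0.091) and only the 4 libraries compared (0.14). It turned to -0.12 with scaling on library size only. Of 19 MHC class I genes, 9 rose, 5 fell and 5 did not pass (camera adjusted p = 0.249). HLA-F (-1.91 ± 0.24) fell, B2M stood at 0.32 ± 0.061, and HLA-A (-0.075 ± 0.091) did not pass. With scaling on library size only, B2M lost its call at 0.052 and HLA-A passed at -0.34. Fatty acid synthesis genes fell: of 13, 2 rose, 11 fell and 0 did not pass. Their median was -0.49 (camera adjusted p = 5.76e-06, adjusted p = 0.0957 with an estimated correlation), or -0.75 with scaling on library size only. SREBF1, the gene of a lipogenic transcription factor (-2.22 ± 0.060), THRSP (-2.42 ± 0.080) and the desaturase gene SCD (-1.16 ± 0.062) were among them. The cholesterol exporter gene ABCG1 fell by 3.51 ± 0.12 on the log2 scale. Of 30 estrogen receptor targets, 6 rose, 17 fell and 7 did not pass (7 rose and 17 fell adjusted over the list alone). Their median was -0.34 (camera adjusted p = 0.0036, adjusted p = 0.234 with an estimated correlation), or -0.60 with scaling on library size only. GREB1 (-0.55 ± 0.070), PGR (-0.82 ± 0.073), TFF1 (-0.98 ± 0.077) and AREG (-1.81 ± 0.082) fell. ESR1 stood at -0.17 ± 0.062, a call lost in 4 of the 6 fits that left out 1 library (-0.17 to -0.10), with DESeq2 (-0.16) and with only the 4 libraries compared (-0.17). Of 26 luminal genes, 8 rose, 8 fell and 10 did not pass (camera adjusted p = 0.987), and TFF3 fell (-1.28 ± 0.072). Of 11 basal and mesenchymal genes, 4 rose, 2 fell and 5 did not pass (camera adjusted p = 0.531), and FN1 fell (-2.47 ± 0.076).

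The reported AP-1 target genes that were measured, 17 of 35 listed, did not move as a group when the AP-1 inhibitor was added. Of these, 6 rose, 6 fell and 5 did not pass (7 rose and 6 fell adjusted over the list alone) (camera adjusted p = 0.795). The ferritin gene FTH1 rose (2.79 ± 0.10), with the limit that its many pseudogenes can share reads. AREG, LAMA3 (-1.49 ± 0.13) and CYR61 (-1.10 ± 0.11) fell. Of 14 AP-1 subunits, 9 rose, 2 fell and 3 did not pass (camera adjusted p = 0.12). Over the alternatives that p ran from 3.72e-05 to 0.29. It was below the threshold only with fry, which asks whether members changed without setting them against other genes. FOS fell (-1.27 ± 0.12), while ATF3 (2.11 ± 0.13), FOSL1 (1.62 ± 0.38), JUND (0.69 ± 0.073) and FOSL2 (0.44 ± 0.067) rose. With scaling on library size only, FOSL2 stood at 0.17 and its call was lost. JUN (0.10 ± 0.061, or -0.16 with that scaling) did not pass, but did without abemaciclib replicate 1 (0.19). The call of JUNB (-0.25 ± 0.085) was lost without abemaciclib replicate 1 (-0.20) or combination replicate 1 (-0.18) and with DESeq2 (-0.24). Of 19 immediate-early genes, 7 rose, 8 fell and 4 did not pass (camera adjusted p = 0.572). MYC (-0.12 ± 0.061) did not pass, but did with scaling on library size only (-0.38), without abemaciclib replicate 2 (-0.16) and among genes with a mean of at least 5 CPM (-0.16). Of 20 retinoic acid response genes, 7 rose, 5 fell and 8 did not pass (camera adjusted p = 0.468). CYP26A1 (2.31 ± 0.45), CYP26B1 (1.45 ± 0.11), DHRS3 (1.93 ± 0.16) and SOX9 (1.30 ± 0.066) rose. The retinoic acid-binding protein gene CRABP1 (-1.68 ± 0.11) fell. Of 8 senescence secretory genes, 3 rose, 3 fell and 2 did not pass (camera adjusted p = 0.356). IGFBP5 (1.25 ± 0.061) rose and LMNB1 (-1.69 ± 0.068) fell. Of 8 anti-apoptotic genes, 3 rose, 0 fell and 5 did not pass (camera adjusted p = 0.572). BCL2 (-0.10 ± 0.074) did not pass, and BCL2L1 stood at 0.30 ± 0.064. With scaling on library size only, BCL2 passed at -0.36 and BCL2L1 lost its call at 0.041. MCL1 stood at 0.15 ± 0.056, a call lost in 3 of the 6 fits that left out 1 library (0.12 to 0.16) and -0.11 with scaling on library size only. That call was also lost with a mean of at least 5 CPM (0.10), a replicate block (0.15) and only the 4 libraries compared (0.15). Of 11 pro-apoptotic genes, 4 rose, 2 fell and 5 did not pass (camera adjusted p = 0.12). HRK (3.05 ± 0.15) and BBC3 (1.17 ± 0.12) rose and BCL2L11 (-0.39 ± 0.083) fell.

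Ribosomal protein genes rose with SR11302: of 40, 40 rose, 0 fell and 0 did not pass. Their median was 0.81 (camera adjusted p = 1.58e-24, adjusted p = 0.271 with an estimated correlation). Their share of reads was 8.94% ± 0.209 (SD, n = 2) in the combination. RPLP1 (1.18 ± 0.079) and RPS23 (1.37 ± 0.080) were examples; processed pseudogenes of this family can share reads. Of 13 mitochondrially encoded transcripts, 8 rose, 2 fell and 3 did not pass (camera adjusted p = 0.0849). MT-ND1 (1.44 ± 0.11) rose and MT-CO3 (-0.78 ± 0.11) fell. Their camera test passed without abemaciclib replicate 1 (adjusted p = 0.0449), DMSO replicate 1 (adjusted p = 0.0484) or combination replicate 1 (adjusted p = 3.96e-05). The combination libraries differed in mitochondrial share (6.28% and 7.85%). Of 25 hypoxia and glycolysis genes, 5 rose, 10 fell and 10 did not pass (camera adjusted p = 0.566), and NDRG1 fell (-0.68 ± 0.067). Markers of other cell types fell: of 5, 0 rose, 3 fell and 2 did not pass. Their median was -1.56 (camera adjusted p = 0.02, adjusted p = 0.24 with an estimated correlation), and the call was lost (adjusted p = 0.0556) with scaling on library size only. Collagen gene COL1A1 (-1.56 ± 0.089) fell, and LUM went from 114 to 23 reads.

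Other large rises were in KLHDC7B (4.66 ± 0.25), NOS3 (3.50 ± 0.19) and FLRT3 (3.35 ± 0.18). Beside IFI6, the largest falls by the naming rule were in CLIC3 (-5.06 ± 0.17), SOWAHA (-4.19 ± 0.17), PADI2 (-4.03 ± 0.11), YBX2 (-3.96 ± 0.28) and SUSD2 (-3.74 ± 0.075). In this comparison edgeR's test called 7635 of 12823 genes (59.5%), of which 3774 rose and 3861 fell. By fold, 409 rose and 1380 fell by more than 2-fold. With scaling by library size only, the median of all genes moved to -0.28 and the calls split into 1802 higher and 6295 lower, so changes are given relative to the TMM scale. With a test against a fold of 1.2, 4933 genes passed. Camera called 12 lists, of which G2/M genes and NRF2 targets held with an estimated correlation. AP-1 target and retinoic acid genes had a camera direction or mean opposite in sign to another of their summaries.

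**Figure D2:**
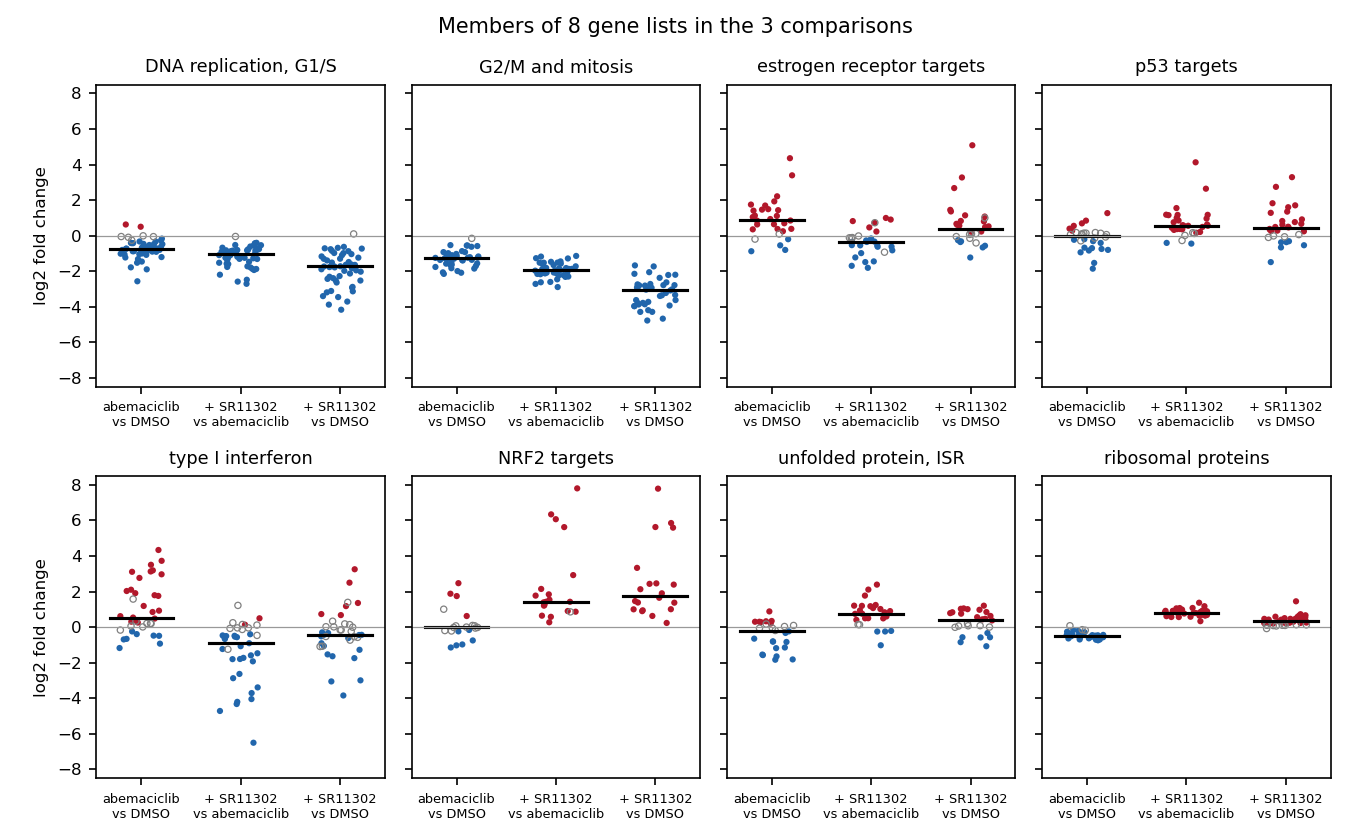
Log2 fold changes of the members of 8 gene lists in the 3 comparisons, with a point per gene (filled red or blue where higher or lower at an adjusted p of 0.05, open grey where not) and a bar at the median of the list; IFI44, with 0 reads in a group, is not drawn. The median of G2/M genes lay below 0 in every comparison (-1.26, -1.94 and -3.06), and that of NRF2 targets above 0 when SR11302 was added (1.43).

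Against DMSO, the combination showed the joint change under both compounds. Cell cycle genes were far below the vehicle level, and NRF2, lysosome, cholesterol synthesis and p53 target genes were mostly above it. Of 40 G2/M genes, 0 rose, 40 fell and 0 did not pass. Their median was -3.06 (camera adjusted p = 2.78e-109, adjusted p = 0.0114 with an estimated correlation). Of 51 DNA replication genes, 0 rose, 50 fell and 1 did not pass. Their median was -1.73 (camera adjusted p = 7.81e-45, adjusted p = 0.0371 with an estimated correlation). TOP2A (-4.19 ± 0.074), NDC80 (-4.77 ± 0.12) and MKI67 (-3.02 ± 0.074) fell in the G2/M list. RRM2 (-4.16 ± 0.079), E2F1 (-1.78 ± 0.092) and CCNE2 (-2.39 ± 0.22) fell in the replication list. Of 15 cyclins, CDKs and inhibitors, 4 rose, 10 fell and 1 did not pass. Their median was -0.69 (camera adjusted p = 0.0302, adjusted p = 0.227 with an estimated correlation). CDK6 (2.51 ± 0.33) and CDKN1A (1.35 ± 0.055) rose. CDK4 (-0.45 ± 0.065), RB1 (-0.69 ± 0.087) and CDKN1B (-1.32 ± 0.062) fell. CCNE1 (0.10 ± 0.22) did not pass. CCND1 stood at 0.23 ± 0.058, a call lost without DMSO replicate 2 (0.21) and -0.021 with scaling on library size only. Of 20 NRF2 targets, 20 rose, 0 fell and 0 did not pass. Their median was 1.78 (camera adjusted p = 1.05e-47, adjusted p = 0.0371 with an estimated correlation). HMOX1 rose from 16.8 ± 1.93 to 834 ± 8.11 CPM (5.63 ± 0.081) and AKR1C1 by 7.79 ± 0.10. Of 30 p53 targets, 20 rose, 6 fell and 4 did not pass. Their median was 0.42 (camera adjusted p = 0.00121, adjusted p = 0.135 with an estimated correlation), or 0.17 with scaling on library size only. GDF15 rose by 3.29 ± 0.063. Of 34 lysosome genes, 23 rose, 4 fell and 7 did not pass. Their median was 0.83 (camera adjusted p = 1.25e-13, adjusted p = 0.135 with an estimated correlation). GPNMB (6.72 ± 0.24), CTSD (2.68 ± 0.077) and SQSTM1 (2.71 ± 0.066) rose.

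Cholesterol synthesis genes were higher: of 24, 18 rose, 2 fell and 4 did not pass. Their median was 0.57 (camera adjusted p = 4.92e-06, adjusted p = 0.135 with an estimated correlation), or 0.32 with scaling on library size only. HMGCS1 rose by 1.59 ± 0.061. Of 13 fatty acid synthesis genes, 6 rose, 6 fell and 1 did not pass (7 rose and 6 fell adjusted over the list alone) (camera adjusted p = 0.794). Their median of 0.12 turned to -0.13 with scaling on library size only. THRSP (1.05 ± 0.10) rose and SREBF1 (-1.70 ± 0.060) fell. Of 30 estrogen receptor targets, 17 rose, 6 fell and 7 did not pass (17 rose and 7 fell adjusted over the list alone). Their median was 0.36 (camera adjusted p = 7.33e-04, adjusted p = 0.135 with an estimated correlation), or 0.11 with scaling on library size only. GREB1 (0.56 ± 0.070), TFF1 (0.48 ± 0.077) and RET (1.14 ± 0.056) were above DMSO, and ESR1 fell (-0.26 ± 0.062). PGR stood at 0.22 ± 0.074, a call lost without DMSO replicate 2 (0.18) or combination replicate 1 (0.14), and -0.030 with scaling on library size only. Interferon response genes did not pass as a list (camera adjusted p = 0.324): of 39, 6 rose, 16 fell and 17 did not pass (6 rose and 15 fell adjusted over the list alone). ISG15 (1.36 ± 0.14) and STAT1 (0.68 ± 0.058) rose and OAS3 (-1.53 ± 0.12) fell. The median was -0.43, or -0.33 with 2 members at or under the floor in both groups set to no change, and -0.68 with scaling on library size only. Of 19 MHC class I genes, 12 rose, 1 fell and 6 did not pass. Their median was 0.43 (camera adjusted p = 0.0358, adjusted p = 0.308 with an estimated correlation), a call also lost without abemaciclib replicate 2 (adjusted p = 0.0517). With scaling on library size only, that median was 0.17. HLA-A stood at 0.67 ± 0.10 and B2M at 0.24 ± 0.060, or -0.012 with scaling on library size only. Of 17 reported AP-1 targets, 9 rose, 4 fell and 4 did not pass. Their median was 0.66 (camera adjusted p = 0.0115, adjusted p = 0.227 with an estimated correlation), a call also lost without abemaciclib replicate 1 (adjusted p = 0.0550) or replicate 2 (adjusted p = 0.0560). With scaling on library size only, that median was 0.41. FTH1 (1.97 ± 0.094) and LAMC2 (3.67 ± 0.18) rose. Of 14 AP-1 subunits, 7 rose, 1 fell and 6 did not pass (camera adjusted p = 0.134). JUNB (0.68 ± 0.089), JUND (0.36 ± 0.072), FOSL1 (1.31 ± 0.36), FOSL2 (1.22 ± 0.069) and BATF (2.70 ± 0.26) rose, and the call of JUND was lost with scaling on library size only (0.10). JUN (0.13 ± 0.061) and FOS (0.14 ± 0.13) did not pass. JUN did without either abemaciclib library (0.13 each) or with only the 4 libraries compared (0.13).

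Of 26 unfolded protein and integrated stress response genes, 14 rose, 6 fell and 6 did not pass (15 rose and 6 fell adjusted over the list alone). Their median was 0.41 (camera adjusted p = 0.0383, adjusted p = 0.524 with an estimated correlation), a call also lost without DMSO replicate 2 (adjusted p = 0.0604) and with scaling on library size only (adjusted p = 0.164, median 0.16). The chaperone gene HSPA5 rose (0.98 ± 0.060). Of 13 mitochondrially encoded transcripts, 11 rose, 1 fell and 1 did not pass. Their median was 1.30 (camera adjusted p = 1.31e-05, adjusted p = 0.445 with an estimated correlation). Their share of reads was 7.06% ± 1.11 in the combination against 4.30% ± 0.162 in DMSO (SD, n = 2). Of 40 ribosomal protein genes, 30 rose, 0 fell and 10 did not pass. Their median was 0.33 (camera adjusted p = 7.33e-04, adjusted p = 0.723 with an estimated correlation), or 0.070 with scaling on library size only. The other lists were not called by camera. Of 19 immediate-early genes, 7 rose, 8 fell and 4 did not pass (camera adjusted p = 0.754). Of 26 luminal genes, 11 rose, 10 fell and 5 did not pass (camera adjusted p = 0.513). Of 11 basal and mesenchymal genes, 5 rose, 2 fell and 4 did not pass (camera adjusted p = 0.907). Of 20 retinoic acid response genes, 10 rose, 6 fell and 4 did not pass (10 rose and 7 fell adjusted over the list alone) (camera adjusted p = 0.0752, and 0.0456 without combination replicate 2). Of 8 senescence secretory genes, 1 rose, 3 fell and 4 did not pass (camera adjusted p = 0.292). Of 8 anti-apoptotic genes, 3 rose, 2 fell and 3 did not pass (camera adjusted p = 0.754). Of 11 pro-apoptotic genes, 5 rose, 4 fell and 2 did not pass (camera adjusted p = 0.77). Of 25 hypoxia and glycolysis genes, 14 rose, 6 fell and 5 did not pass (camera adjusted p = 0.134). Of 5 markers of other cell types, 1 rose, 2 fell and 2 did not pass (camera adjusted p = 0.665). Hypoxia and glycolysis genes had a median of 0.25, or -0.0044 with scaling on library size only, and pro-apoptotic genes 0.16, or -0.091. The values were 0.55 ± 0.076 for BCL2, 0.40 ± 0.064 for BCL2L1, 0.29 ± 0.056 for MCL1, -0.66 ± 0.060 for MYC and 3.48 ± 0.52 for CYP26A1, all past the threshold. With scaling on library size only, BCL2L1 (0.14) and MCL1 (0.040) lost their calls. DHRS3 stood at 0.45 ± 0.13, and its call was lost without DMSO replicate 2 (0.35) or combination replicate 1 (0.37) and with scaling on library size only (0.19).

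By the naming rule, the largest falls against DMSO beside NDC80 were in YBX2 (-5.83 ± 0.22), the chromatin protein gene HMGB2 (-5.07 ± 0.079), MND1 (-4.84 ± 0.19), NFATC4 (-4.74 ± 0.23) and the mitotic kinase gene AURKB (-4.67 ± 0.13). CYP26B1 (4.94 ± 0.16) was among the largest rises. The normalised ratio of CYP1A1, from 1 read in DMSO to 1433, was 1810 (95% counting interval 324 to 71558). Such intervals and the floors used for genes at 0 reads cover counting error only. The edgeR test called 8480 of 12823 genes (66.1%), 4217 higher and 4263 lower, of which 984 and 1286 by more than 2-fold. Scaling by library size only moved the median of all genes to -0.26 and gave 2549 higher and 6206 lower. Camera called 13 lists, of which DNA replication genes, G2/M genes and NRF2 targets held with an estimated correlation. The median, mean and camera direction differed in sign for immediate-early, luminal, senescence, fatty acid, hypoxia, anti-apoptotic and other cell type genes.

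Many genes moved one way with abemaciclib and the other way when SR11302 was added. All 8 fatty acid synthesis genes that rose with abemaciclib fell with SR11302, as did 20 of the 23 interferon response genes and 14 of the 24 estrogen receptor targets. All 37 ribosomal protein genes and 12 of 13 stress response genes that fell with abemaciclib rose back. Cell cycle genes did not: 39 of 39 G2/M genes and 43 of 44 DNA replication genes that fell with abemaciclib fell further. Nor did most lysosome genes: of 21 that rose with abemaciclib, 13 rose further and 2 fell. Of 14 cholesterol synthesis genes that rose, 9 rose further and 2 fell, while all 4 that fell rose back. Of 12 mitochondrially encoded transcripts that rose, 7 rose further and 2 fell. CLIC3, a chloride channel gene, went up by 4.36 ± 0.15 and then stood at -5.06 ± 0.17. UNC5B, a netrin receptor gene picked here after its values were seen, stood at -2.53 ± 0.10 with abemaciclib and 2.53 ± 0.10 with SR11302 added. Of 5271 genes called in both comparisons, 3510 (66.6%) moved in opposite directions, 1780 up then down and 1730 down then up. Independent lists would give 1218 and 1186. The other 1761 moved the same way, 891 up and 870 down, where independent lists would give 1190 and 1213. Of 1179 genes that abemaciclib raised by more than 2-fold, 692 (58.7%) fell with SR11302, 127 rose further and 360 did not pass. Of 672 that it lowered by more than 2-fold, 223 (33.2%) rose back, 240 fell further and 209 did not pass. Among all 12823 tested genes, 3774 rose and 3861 fell with SR11302. Against these shares, falls were far more common among genes raised more than 2-fold, but rises were little more common among those lowered more than 2-fold. That contrast did not extend to all called genes: 1780 of 4044 raised genes fell and 1730 of 4028 lowered genes rose.

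Both comparisons share the abemaciclib libraries with opposite signs. In 20 simulations of unchanged groups sharing those libraries, 0.05 genes on average, and at most 1, were called in opposite directions. Since few genes pass in either comparison when no group changes, that count cannot show how many opposite calls in the data come from sharing. Across 12823 genes, which are not independent replicates, the log2 fold changes correlated at -0.31, against -0.49 in simulation. Their covariance was -0.23 against -0.018, a difference of -0.21. With 1 abemaciclib library given to each comparison, a test chosen after the results were seen, 3064 or 3241 genes were called in opposite directions. The covariance was then -0.19 or -0.21, over 12918 genes. Each comparison then held 1 abemaciclib library only, so part of the excess in the full counts may come from the shared libraries. The labels do not say that libraries of a group were separate cultures. If they were not, a deviation of their culture would remain in both comparisons after such a split. With a test against a fold of 1.2, 1810 genes moved in opposite directions. The comparisons against the shared DMSO libraries called 5980 genes in common, 5070 in the same direction and 910 in opposite directions. Of the former, 2489 were up and 2581 down, where independent lists would give 1330 and 1339. Their correlation was 0.56 against 0.47 in simulation, and their covariance 0.49 against 0.017, a difference of 0.47. With 1 DMSO library given to each, 3987 or 4045 genes were called in the same direction, and the covariance was 0.50 or 0.49. Here too, each comparison held 1 DMSO library, and part of the excess in the full counts may come from the shared libraries. The covariance, in contrast, was no lower than with both DMSO libraries shared. It was taken over 13044 genes in the split and 12823 in the full fit, so these values are not strictly comparable.

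**Figure D3:**
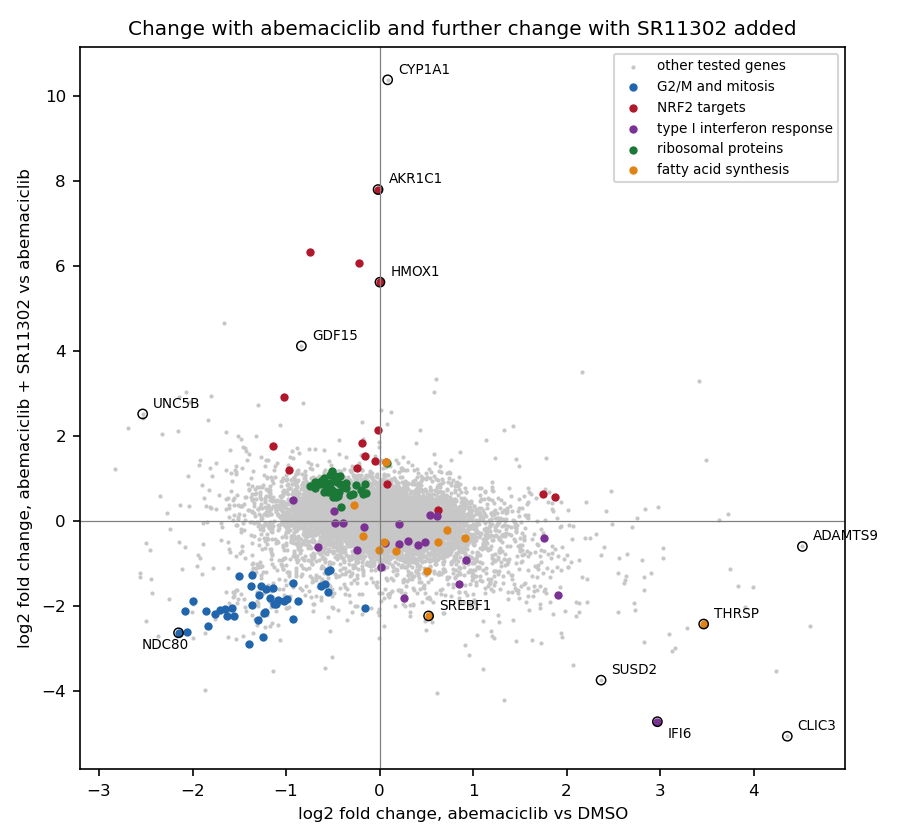
Log2 fold change with abemaciclib (abemaciclib vs DMSO, horizontal) against the further change with SR11302 added (abemaciclib + SR11302 vs abemaciclib, vertical) for 10127 genes with a mean of at least 5 CPM, with 5 gene lists coloured and named genes circled. Of the measured list members, 39 of 40 G2/M genes fell in both comparisons (lower left), and 37 of 40 ribosomal protein genes fell and then rose (upper left). By the same calls, 20 of 39 interferon response genes, among them IFI6 (2.97 and -4.71), and 8 of 13 fatty acid synthesis genes, among them THRSP (3.47 and -2.42), rose and then fell (lower right).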

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

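The test against a fold of 1.2, the fits without mitochondrially encoded genes, the crossed block and the split of the abemaciclib libraries were tests chosen only after the results were seen. Counts of changed genes stayed within 1.5 times the reported ones in 67 pairings of a count with an alternative; the 2 exceptions, under the test against a fold of 1.2, were 4933 genes for SR11302 added to abemaciclib and 1810 genes moving in opposite directions, fewer because that test asks for a larger change, while the other counts were 5441 and 6022. DESeq2 called 6992, 6595 and 7543 genes for abemaciclib against DMSO, the combination against abemaciclib and the combination against DMSO, and limma-voom 8127, 7599 and 8446. Leaving out each library in turn gave 6641 to 8058, 6378 to 7548 and 7222 to 8929 genes; a group left with 1 library is assumed to vary like the others. Values for named genes kept their direction and their side of the threshold in 6515 cases; 95 lost the call, 15 gained it and 7 reversed. All reversals came with scaling by library size only, which by its construction ignores composition: MCL1 -0.11, CDK4 -0.0012, JUN -0.16 and STAT1 -0.12 with SR11302 added, and CCND1 -0.021, PGR -0.030 and B2M -0.012 for the combination against DMSO. List tests stayed on their side in 794 cases, 39 lost the call and 67 gained it; 32 of the losses came with an estimated correlation, and 38 and 23 of the gains with fry in either and in one direction, which does not set a list against other genes. A replicate block gave 7903, 7449 and 8346 genes and changed no list call but that of mitochondrially encoded transcripts with SR11302 added (adjusted p = 0.0471). Samples share only a number: deviations of same-numbered libraries correlated, across genes, at 0.0030 for DMSO with abemaciclib, -0.019 for DMSO with the combination and -0.20 for abemaciclib with the combination. With the numbers of the combination crossed in the replicate block, 8271, 7866 and 8675 genes were called.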

Other observations

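The tests on 8 further gene lists, of scaling, and of the list without aldo-keto reductases were chosen only after the results were seen. Heat shock genes, which encode protein-folding chaperones, rose in each comparison: of 14, 11 rose, 1 fell and 2 did not pass with abemaciclib (median 0.55, camera adjusted p = 3.99e-05, adjusted p = 0.403 with an estimated correlation), 11 rose, 3 fell and 0 did not pass with SR11302 added (median 0.40, camera adjusted p = 0.00328, adjusted p = 0.332 with an estimated correlation), and 14 rose, 0 fell and 0 did not pass for the combination against DMSO (median 0.97, camera adjusted p = 7.76e-09, adjusted p = 0.332 with an estimated correlation). HSPH1 changed by 0.74 ± 0.066 and then 1.15 ± 0.063, and HSP90AA1 by 0.45 ± 0.064 and then 0.72 ± 0.064. Aminoacyl-tRNA synthetase genes, which charge tRNAs for translation, moved down and then up: of 20, 4 rose, 15 fell and 1 did not pass with abemaciclib (median -0.50, camera adjusted p = 1.73e-05, adjusted p = 0.122 with an estimated correlation), and 18 rose, 0 fell and 2 did not pass with SR11302 added (median 0.52, camera adjusted p = 2.82e-08, adjusted p = 0.0641 with an estimated correlation). SARS went by -1.15 ± 0.062 and then 0.97 ± 0.062, and WARS by -0.76 ± 0.057 and then 1.40 ± 0.058. Of 32 proteasome subunit genes, 22 rose, 3 fell and 7 did not pass with SR11302 added (median 0.27, camera adjusted p = 0.00513, adjusted p = 0.61 with an estimated correlation). The further lists were fitted on the TMM scale only. With scaling on library size only, the median of all genes with SR11302 added was -0.28. A proteasome median of 0.27 is of about that size, so this rise holds only relative to the TMM scale. With abemaciclib, 8 proteasome genes rose, 9 fell and 15 did not pass (camera adjusted p = 0.918). Nuclear-encoded respiratory chain genes did not pass as a list with abemaciclib (8 rose, 11 fell and 14 did not pass, camera adjusted p = 0.93) or with SR11302 added (13 rose, 4 fell and 16 did not pass, camera adjusted p = 0.192). Of 9 metallothioneins listed only 2 were measured, too few for a statement (camera adjusted p = 0.559 with SR11302 added).

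CYP1B1, another P450 gene induced through the aryl hydrocarbon receptor (AHR), rose with SR11302 from 71.3 ± 1.87 to 314.6 ± 8.04 CPM (2.14 ± 0.060); it was chosen after its values were seen, and with CYP1A1 it prompted a test of other AHR targets. Of 7 measured, 6 rose, 0 fell and 1 did not pass (median 2.002, camera adjusted p = 4.94e-04, adjusted p = 0.124 with an estimated correlation), including the AHR repressor gene AHRR (2.002 ± 0.31) and NEDD9 (1.85 ± 0.14), while TIPARP (0.25 ± 0.11) did not pass. ALDH3A1 went from 0 to 142 reads, at least 55.4-fold higher against the floor of 3 counts over the group, and the list median was the same with it at that bound. A candidate explanation is AHR activation in the cells given SR11302, which rests on a median of 2.002 over few genes and on a call that an estimated correlation removes. The falls of ABCG1 and SREBF1 prompted the same question for targets of the liver X receptor (LXR). The desaturase gene SCD, which also fell, was left out of that list as well. Of 6 others measured, 1 rose, 5 fell and 0 did not pass (median -0.50, camera adjusted p = 0.192, adjusted p = 0.399 with an estimated correlation), which leaves open whether these targets fell together.

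G2/M genes fell further when SR11302 was added. The list median was -1.93 at its highest and -2.20 at its lowest over TMM, RLE and library-size scaling. These scalings differed little, with a median of all genes from -0.28 to -0.0043. They could not have brought the list near 0, so scaling as a cause is not tested beyond that range. Transcript length and GC content are argued against: against 726 genes matched on length, GC content and expression, the list stood at -2.003 (bootstrap SE 0.0823), and the matched genes at 0.053. That SE comes from resampling genes and does not cover the spread between libraries. A stronger block of proliferation in cells given both compounds may account for the fall. Whether SR11302 alone lowers these genes, through AP-1 or otherwise, stays open, since a group given SR11302 alone was not analysed here.

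NRF2 targets rose when SR11302 was added. The rise was not limited to the aldo-keto reductase paralogs, which can share reads. The list without AKR1C1, AKR1C2, AKR1C3 and AKR1B10 kept a median of 1.32, with 15 of 16 members rising. Since 19 of 20 members of the full list rose, that outcome was largely set beforehand and restates the list result. The list median was 1.16 at its lowest and 1.44 at its highest over the 3 scalings. The scalings differed too little to remove a rise of this size, so scaling as a cause is not tested beyond that range. An NRF2 response to SR11302 at 20 uM may account for the pattern, and whether it needs abemaciclib stays open for want of SR11302 alone.

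Ribosomal protein genes fell with abemaciclib and rose when SR11302 was added. Length and GC content are argued against as the whole cause: relative to 193 matched genes the list stood at -0.52 (bootstrap SE 0.0481) with abemaciclib and 0.52 (bootstrap SE 0.0596) with SR11302, although the matched genes themselves stood at 0.29 in the latter and were less expressed (median 554 against 1292 CPM). These SEs come from resampling genes as if independent. They cover neither the shared movement of the list (estimated inter-gene correlation 0.89 and 0.88) nor the spread between libraries. Over TMM, RLE and library-size scaling, medians were no higher than -0.47 with abemaciclib and no lower than 0.55 with SR11302. These scalings differed too little to bring either median near 0, so scaling as a cause is not tested beyond that range. Of 17 other mRNAs with a 5' terminal oligopyrimidine tract (5'TOP), 0 rose, 17 fell and 0 did not pass with abemaciclib (median -0.50, camera adjusted p = 2.11e-06, adjusted p = 0.403 with an estimated correlation), and 16 rose, 0 fell and 1 did not pass with SR11302 (median 0.79, camera adjusted p = 6.87e-13, adjusted p = 0.195 with an estimated correlation). The pattern was thus shared by other 5'TOP mRNAs, medians -0.50 and 0.79, which describes its extent and not its cause. These 17 mRNAs were not set against genes matched on length, GC content and expression. RNA quality or handling that differs between groups stays open because the labels give no measure of it.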
